A study of Mus musculus with 20 samples.

How the data were processed

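Liver RNA from 20 male mice was measured on 20 single-colour (Cy3) Agilent whole-mouse arrays, annotated on mm8, on 6 slides. The 4 groups of 5 mice were wild-type or LXR knockout on normal or Western diet for 7 weeks. Per the file headers, the authors extracted each scan with Agilent Feature Extraction 9.5.3.1 (protocol GE1-v5_95_Feb07, GenePix scanner), and the processed signal is an intensity after background subtraction with a spatial and a multiplicative detrend, in which dim spots carry a surrogate. The deposited series matrix is on a log2 scale, and the submitters' notes name Feature Extraction 9.5 and limma without a version. Each of its columns had r above 0.997, across probes, with log2 of the median signal of its array. Its 5%, 25%, 50%, 75% and 95% quantiles differed by at most 0.07 between arrays, against 0.825 to 2.15 in log2 of the processed signal of the same probes, from which a quantile normalization was inferred. The arrays are single-colour, so no ratio direction applies. How 24493 of 41174 probes were chosen for it stays unknown. Column medians of the matrix were 7.766, 7.767, 7.776, 7.778 and 7.783 in wild-type mice 1 to 5 on normal diet, and 7.761, 7.760, 7.770, 7.765 and 7.778 on Western diet. In knockout mice 1 to 5 they were 7.755, 7.764, 7.758, 7.766 and 7.759 on normal diet and 7.737, 7.734, 7.735, 7.747 and 7.739 on Western diet.

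The 43379 non-control spots of each array were averaged per probe (245 probes had 10 spots). Before this 105 to 270 spots per array marked by the extraction software as foreground outliers were left out, which left 1855 probe values missing. The 1639 control spots were not used. Values were log2 of the processed signal minus the 75th percentile of the array. Probes were named through their RefSeq accession (23374), a current symbol (6733) or a synonym (2919), and 8148 kept the name of the file. Of 27573 gene names, 8955 had more than 1 probe, and the probe with the highest mean over all 20 arrays stood for the gene. Called probes of a gene went in opposite directions for 26, 249, 1, 158 and 18 genes in the 5 comparisons, in the order given in the results. Genes were kept where the probe was well above background on at least 4 of 5 arrays of at least 1 group (17552 genes). In the results a named gene is given with the number of arrays of a group on which it was well above background where this was under 5. In the 5 comparisons 326, 610, 77, 348 and 493 called genes lay below background on every array of a group.

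Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the package data.table, version 1.17.8, in 1 fit of 4 group means with 16 residual and 2.23 prior degrees of freedom. Benjamini-Hochberg adjustment was made within each of 5 comparisons, with a threshold of adjusted p under 0.05. The comparisons were the genotype difference on each diet (knockout minus wild-type), the diet difference in each genotype (Western minus normal) and the difference between the diet differences (knockout minus wild-type). Before the data were examined, 26 gene lists were written from general knowledge, and camera from limma tested each with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The LXR target list was tested only with the deleted Nr1h3 in it. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

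Genes named in the text came from a rule fixed at the same time. It allowed Nr1h3, Nr1h2 and 11 genes of LXR-dependent lipid metabolism in every comparison, the genes with the largest and smallest differences of each comparison, and up to 4 members of each list with the largest differences. It made 521 gene values eligible, of which 207 are named, and these were picked by function and for length after their values had been seen. The pick favoured stable genes: 145 of 184 named calls (78.8%) but 269 of 482 eligible calls (55.8%) held under every alternative, so that the named genes overstate how firm a typical call is. Slides were used as a block, and values within slides were taken on slides that held both groups. Alternatives covered scaling (median, quantile), background correction (normexp with an offset of 50), the series matrix, filters, probe choice, moderation, array weights, slide and replicate-number blocks, the groups in the fit and leaving out each array. On 17540 genes simulated as independent, the test called 22.4%, 58.2% and 81.8% of genes changed by log2 0.5, 1 and 2 for genotype on normal diet. For the interaction it called 3%, 40.3% and 71.2%, and 4 to 7 of 17340 unchanged genes were called in each comparison. There the shifted list had adjusted p = 1.19e-46 and 0 of 25 other lists were called, which does not test correlated genes.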

Results

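The data were gene expression profiles of liver from 20 male mice aged 28 weeks, in 4 groups of 5 mice by genotype and diet. Wild-type mice and mice lacking both liver X receptors (LXR), nuclear receptors that sense oxidised cholesterol, ate normal chow or a Western diet for 7 weeks, and the replicates were different mice according to the design text. Each liver had its own array, and these lay on 6 slides. The 75th percentile of the processed signal ran from 170.3 to 435.1 intensity units per array, and on Western diet from 339.7 to 435.1 in knockout and 261.1 to 330.8 in wild-type arrays. Between 53.6% and 67.12% of probes lay well above background. Correlations of replicates within a group, across genes, were between 0.9534 and 0.9908.

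The first principal component held 57.6% of the variance of the 17540 genes with a value on every contrast, and the second held 11.2%. Knockout mice on Western diet lay at 86.6 to 144.7 on the first component, apart from the other 3 groups. Values below are log2 differences in signal ± SE with 5 mice per group unless a smaller n is stated. "Rose", "fell" and "changed" mean that the adjusted p lay under 0.05. For a list, counts adjusted over it alone are given where they differ from those over all genes (marked alone for lists that did not pass). A range after the median of a called list is that within single slides with both groups. Next is the most distant median over the alternatives, except leaving out an array, where over 1.5 times away. Bounded is the median with genes below background in 1 group set at their bound. For a gene well above background on 1 or 2 of 5 arrays of a group, floored is the difference with dim values raised to the floor of their array (defined below).

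**Figure D1:**
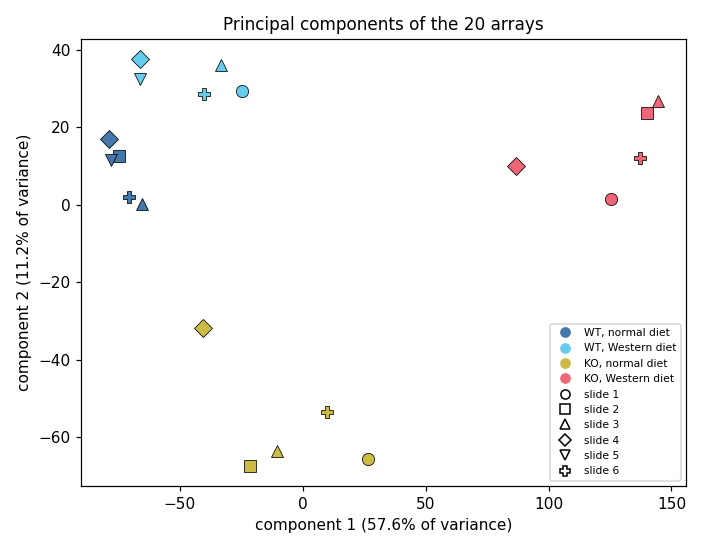
The 20 arrays on the first (57.6% of variance) and second (11.2%) principal components, with colour for the group and marker for the slide.

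The targeted genes were low in knockout mice. Nr1h3 (LXR alpha), measured by 1 probe on chromosome 2 at 90985117 to 90985176 of mm8, was at 4.53 ± 0.14 (SD) in wild-type mice on normal diet and -4.52 ± 0.54 (SD) in knockout mice. The Nr1h3 difference was -9.05 ± 0.29 on normal diet (adjusted p = 3.02e-13) and -9 ± 0.29 on Western diet (adjusted p = 1.67e-13). Nr1h2 (LXR beta), measured by 1 probe on chromosome 7 at 44417972 to 44418031, differed by -5.39 ± 0.31 on normal diet (adjusted p = 1.05e-09) and -5.43 ± 0.31 on Western diet (adjusted p = 1.5e-10). Both probes were near background in knockout mice, well above it on 4 of 5 arrays for Nr1h3 in each knockout group and for Nr1h2 on normal diet. Diet and interaction values of these 2 genes are therefore not given.

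The comparison of genotypes on normal diet asked which liver transcripts depend on LXR without a cholesterol load. Scd1, the desaturase that makes oleic acid, fell (-3.46 ± 0.44, adjusted p = 2.22e-05, saturated on 1 of 5 wild-type arrays), and the acetyl-CoA carboxylase gene Acacb fell (-3.16 ± 0.30, adjusted p = 1.07e-06). The macrophage-secreted protein gene Cd5l fell (-6.61 ± 0.38, adjusted p = 1.12e-09). In all 1988 genes rose and 1472 fell of 17547 tested (19.7% changed), and 1253 of the higher and 382 of the lower genes differed at least 2-fold.

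Among lipid genes, Srebf1, which encodes the main activator of fatty acid synthesis, fell (-0.67 ± 0.23, adjusted p = 0.0485), and so did Mylip (-0.79 ± 0.19, adjusted p = 0.00735), while Abcg1 rose (1.34 ± 0.29, adjusted p = 0.00281). Abca1 (-0.18 ± 0.13, adjusted p = 0.36), Abcg5 (0.44 ± 0.36, adjusted p = 0.436), Abcg8 (-0.02 ± 0.29, adjusted p = 0.97), Fasn (-0.94 ± 0.53, adjusted p = 0.264) and Cyp7a1 (1.58 ± 1.13, adjusted p = 0.353) did not pass the threshold, with n of 3 and 2 for Fasn and 3 and 4 for Abcg5 in wild-type and knockout mice. The same held for Ppara (0.10 ± 0.26, adjusted p = 0.814), Cpt1a (0.27 ± 0.24, adjusted p = 0.452) and the fatty acid transporter gene Cd36 (0.97 ± 0.37, adjusted p = 0.0766). Of 16 LXR target genes, 1 rose and 4 (Nr1h3 included) fell (2 and 4 alone), median -0.23. Of 24 fatty acid synthesis genes, 1 rose and 8 fell (1 and 9 adjusted over the list alone), median -0.49 (-0.90 to -0.06), adjusted p = 0.00368 (p = 0.559 with estimated correlation). Me1 fell (-2.31 ± 0.48, adjusted p = 0.00208), and Scd2 rose (3.08 ± 0.27, adjusted p = 3.67e-07). Of 25 cholesterol synthesis and uptake genes, 11 rose and 0 fell (14 and 0 adjusted over the list alone), median 0.66 (0.19 to 0.87), adjusted p = 3.46e-06 (p = 0.388 with estimated correlation). Idi1 (1.28 ± 0.33), Msmo1 (1.23 ± 0.26) and Cyp51 (1.18 ± 0.32) rose (adjusted p up to 0.0135).

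Of 24 bile acid synthesis and transport genes, 6 rose and 4 fell, with a median of -0.12, mean 0.07, test pointing up. The transporter gene Slco1a4 rose (2.37 ± 0.32, adjusted p = 4.32e-05) and the bile salt export pump gene Abcb11 fell (-0.79 ± 0.13, adjusted p = 0.000309, n of 4 in knockout mice). Of 30 fatty acid oxidation and PPAR alpha target genes, 3 rose and 2 fell, with a median of -0.14, mean 0.00, test pointing down. Of 22 lipid droplet and triglyceride storage genes, 2 rose and 2 fell, with a median of -0.19. The lipid droplet coat gene Plin2 fell (-1.33 ± 0.15, adjusted p = 1.12e-05, n of 4 in knockout mice). In the other metabolic lists that did not pass, genes that rose and fell were lipoprotein (2 and 3 of 24, median -0.18, mean 0.05, test pointing down), glucose (1 and 3 of 21, 2 and 4 alone, median -0.11) and oxidative stress (2 and 2 of 15, 3 and 3 alone, median 0.12), and unfolded protein (2 and 4 of 17, median -0.38), acute phase (1 and 2 of 20, median -0.13, mean 0.30, test pointing down) and hepatocyte (0 and 0 of 15, median -0.17). Of 23 cytochrome P450 and drug metabolism genes, 10 rose and 0 fell, median 0.66 (0.61 to 0.99, 0.61 bounded, 0.30 with normexp), adjusted p = 0.000212 (p = 0.252 with estimated correlation). Cyp2b10, a target of the xenobiotic receptor CAR, rose (1.91 ± 0.49, adjusted p = 0.0103). Of 17 female-biased genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone), median 1.91 (1.39 to 2.16, 1.41 bounded, 0.47 with normexp without outliers), adjusted p = 3.51e-07 (p = 0.00196 with estimated correlation). The female-biased Cyp2b9 (4.28 ± 0.53, adjusted p = 1.73e-05) and Cyp2b13 (3.67 ± 0.58, adjusted p = 0.000196) rose, and Abcd2 was at least 2.41-fold higher (adjusted p = 1.88e-05). Of 13 male-biased genes, 0 rose and 3 fell, median -0.42 (-0.82 to -0.20), adjusted p = 0.0263 (p = 0.586 with estimated correlation). Hsd3b5, a steroid dehydrogenase gene of male liver, fell (-2.23 ± 0.64, adjusted p = 0.0189). An at-least fold is the mean of the brighter group over the mean of the dim group, with each value of the dim group raised to the lowest signal that its array showed among probes well above background.

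Of 23 cell cycle genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone), median 1.70 (0.96 to 3.16, 1.22 bounded, 0.60 with normexp), adjusted p = 4.59e-13 (p = 0.252 with estimated correlation). The proliferation marker Mki67 rose (3.28 ± 0.40, adjusted p = 1.6e-05) and Cdk1 was at least 3.66-fold higher (adjusted p = 0.000338). Of 26 macrophage marker genes, 11 rose and 2 fell (14 and 4 adjusted over the list alone), median 1.01 (0.23 to 2.06), adjusted p = 0.000337 (p = 0.586 with estimated correlation). The integrin gene Itgax rose (4.31 ± 0.47, 4.19 floored, adjusted p = 4.34e-06), measured on 2 of 5 wild-type arrays. The Kupffer cell lectin gene Clec4f fell (-3.88 ± 0.84, adjusted p = 0.00291), as did Cd163 (-5.30 ± 0.51, -4.67 floored, adjusted p = 1.26e-06), measured on 2 of 5 knockout arrays. Of 15 T and B cell marker genes, 8 rose and 0 fell (10 and 1 adjusted over the list alone), median 1.2 (0.48 to 1.85, -0.23 for genes above background on all arrays), adjusted p = 0.00107 (p = 0.252 with estimated correlation). Cd79b (2.79 ± 0.31) and Cd52 (2.71 ± 0.46) rose (adjusted p up to 0.000381). Of 20 interferon response genes, 3 rose and 0 fell (1 and 0 adjusted over the list alone), median 0.79 (0.07 to 1.51, 0.49 blocked), adjusted p = 0.00368 (p = 0.697 with estimated correlation). Of 21 stellate cell and fibrosis genes, 4 rose and 0 fell, median 0.67 (0.00 to 0.48, 0.45 bounded, 0.32 with normexp without outliers), adjusted p = 0.00164 (p = 0.559 with estimated correlation). Of 11 cholangiocyte and progenitor genes, 3 rose and 0 fell (8 and 1 adjusted over the list alone), median 0.81 (0.37 to 1.2, 0.78 bounded, 0.27 with normexp without outliers), adjusted p = 0.0076 (p = 0.559 with estimated correlation). Of 7 red blood cell genes, 3 rose and 0 fell, median 0.51 (0.12 to 0.88, 0.19 on 3 slides), adjusted p = 0.0155 (p = 0.388 with estimated correlation). Cell markers that did not pass were neutrophil (0 and 0 of 10, median 0.25, 0.00 bounded), endothelial (2 and 0 of 15, 1 and 0 alone, median 0.23) and adipocyte (0 and 0 of 4, median -0.11, mean 0.33, test pointing down). Of 19 circadian clock genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone), median 0.59 (0.59 to 1.68, 0.52 bounded, 0.37 with normexp), adjusted p = 0.00395 (p = 0.279 with estimated correlation). Usp2 (4.16 ± 0.40) and Per1 (2.06 ± 0.36) rose, and Ciart was at least 7.42-fold higher, with adjusted p up to 0.000466, while the clock activator gene Arntl fell (-2.36 ± 0.75, adjusted p = 0.0336). The 13 lists that did not pass the list test had adjusted p from 0.0554 to 0.998, and the female-biased list alone passed with an estimated correlation.

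Dct, a pigment cell enzyme gene on chromosome 14, was at least 348-fold lower in knockout mice (adjusted p = 1.09e-12). Nlrp12 fell (-7.62 ± 0.92, -7.09 floored, adjusted p = 1.37e-05), measured on 1 of 5 knockout arrays. The interferon-inducible gene Ifi202b on chromosome 1 was at least 25.9-fold higher (adjusted p = 1.9e-12), and Cd244a at least 35.1-fold higher (adjusted p = 4.48e-09).

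With slides as a block, 1925 genes rose and 1647 fell, all 13 lists kept their call with medians moved by at most 0.30, and 91.7% of called genes had the same direction on each of the 4 slides that held both groups. Of the 36 named genes that were called, 34 were called with the slide block (not Srebf1 or Arntl), and Me1, Abcg1, Mylip and Arntl changed sign on a slide. Without knockout normal-diet mouse 1 the count of lower genes was 967. The call on Srebf1 was lost without any 1 of wild-type normal-diet mice 1 to 4 or of the 10 knockout mice (adjusted p 0.0522 to 0.12). The male-biased list was not called without wild-type normal-diet mouse 4 (median -0.32, adjusted p = 0.0655), and the fibrosis median was 0.39 without knockout normal-diet mouse 1.

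Single mice decided other calls on normal diet. Arntl was not called without 1 of wild-type normal-diet mice 1, 3, 4 and 5 or knockout normal-diet mice 1, 2 and 3 (-2.39 to -1.93, adjusted p 0.0552 to 0.104), nor Hsd3b5 without knockout normal-diet mouse 1 or 2 (-2.05 and -1.92, adjusted p 0.0541 and 0.0538). The endothelial list was called without wild-type normal-diet mouse 3, 4 or 5, knockout normal-diet mouse 2 or 3 or knockout Western-diet mouse 2, 4 or 5 (medians 0.23 to 0.41, adjusted p 0.00521 to 0.0484). The LXR target list, with the deleted Nr1h3 in it, was called without knockout normal-diet mouse 2 (-0.26, adjusted p = 0.0426). The unfolded protein list was called without knockout normal-diet mouse 4 (-0.50, adjusted p = 0.0191). Calls were lost for the male-biased list with quantile normalization (-0.32, adjusted p = 0.0758), the cholangiocyte list with series matrix values (0.40, adjusted p = 0.0693) and the red blood cell list with normexp (0.29, adjusted p = 0.0895). With normexp fitted without outlier spots 1090 genes were higher and 1197 lower (47.7% higher against 57.5%), and among genes above background on all 20 arrays 1319 and 1340.

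On Western diet the same genotype comparison asked what LXR do under a cholesterol load. Scd1 fell (-6.31 ± 0.44, adjusted p = 1.87e-09, saturated on 4 of 5 wild-type arrays), as did Srebf1 (-3.34 ± 0.23, adjusted p = 1.83e-09), Fasn (-3.59 ± 0.48, adjusted p = 0.000131) and the biliary cholesterol exporters Abcg5 (-2.25 ± 0.36, adjusted p = 0.000164) and Abcg8 (-3.62 ± 0.29, adjusted p = 1.15e-08). Fasn values came from 3 arrays in each group, and Abcg5 from 4 wild-type and 3 knockout arrays, after spots marked as outliers were left out. Gpnmb, a gene of lipid-laden macrophages, rose (11.46 ± 0.87, 10.40 floored, adjusted p = 4.86e-09), measured on 1 of 5 wild-type arrays, and the collagen gene Col1a1 rose (5.36 ± 0.47, adjusted p = 2.81e-08). Elovl3, a fatty acid elongase gene of male liver, fell (-10.33 ± 1.2, -9.21 floored, adjusted p = 8.36e-07), measured on 1 of 5 knockout arrays. Counts were 4386 higher and 5742 lower of 17545 genes tested (57.7% changed), with at least 2-fold differences in 2861 and 1995.

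Among LXR targets Abca1 fell less (-0.71 ± 0.13, adjusted p = 0.000128), and Cyp7a1 did not pass (-2.56 ± 1.13, -1.79 floored, adjusted p = 0.0595, 4 of 5 wild-type and 2 of 5 knockout arrays). Of 16 LXR target genes, 3 rose and 10 (Nr1h3 included) fell (3 and 11 adjusted over the list alone). Their median was -1.33 (-1.43 to -0.89), adjusted p = 0.00719 (p = 0.389 with estimated correlation). Of 24 fatty acid synthesis genes, 1 rose and 21 fell, median -1.31 (-1.79 to -0.80), adjusted p = 6.1e-06 (p = 0.341 with estimated correlation). Me1 also fell (-3.93 ± 0.48, adjusted p = 1.48e-06). Of 25 cholesterol genes, 0 rose and 19 fell, median -1.17 (-1.32 to -0.42), adjusted p = 0.000121 (p = 0.389 with estimated correlation). Tm7sf2 (-3.35 ± 0.22) and Cyp51 (-2.54 ± 0.32) fell (adjusted p up to 2.15e-06). Of 24 bile acid genes, 5 rose and 15 fell (5 and 16 adjusted over the list alone), median -1.17 (-1.61 to -0.70), adjusted p = 0.00793 (p = 0.389 with estimated correlation). The oxysterol hydroxylase gene Cyp7b1 (-4.59 ± 0.23) and the bile acid uptake transporters Slc10a1 (-2.99 ± 0.31) and Slco1a1 (-8.74 ± 0.69, -7.84 floored) fell. Slco1a1 was measured on 1 of 5 knockout arrays. The exporter gene Abcc4, near Dct, rose (3.27 ± 0.17). The highest adjusted p of these 4 was 1.87e-07.

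Of 30 fatty acid oxidation genes, 0 rose and 21 fell (0 and 22 adjusted over the list alone), median -0.90 (-1.13 to -0.62, -0.55 with quantile normalization), adjusted p = 8.51e-05 (p = 0.389 with estimated correlation). Cyp4a10 (-4.45 ± 0.25), Acot1 (-3.79 ± 0.49) and Ehhadh (-2.49 ± 0.26), classical targets of PPAR alpha, fell with adjusted p up to 3.81e-06. Ppara fell (-0.96 ± 0.26, adjusted p = 0.00344), and Cpt1a did not pass the threshold (0.43 ± 0.24, adjusted p = 0.134). Cidec (3.52 ± 0.35), Cidea (3.38 ± 0.48) and Cd36 (2.40 ± 0.37) rose, and Fitm1 fell (-3.50 ± 0.54, -2.51 floored, measured on 2 of 5 knockout arrays), adjusted p up to 2.4e-05. Cyp1a2 (-2.70 ± 0.23) and Cyp2c29 (-2.35 ± 0.16) fell (adjusted p up to 2.33e-08). Of 13 male-biased genes, 0 rose and 13 fell, median -4.53 (-5.02 to -3.42), adjusted p = 6.9e-08 (p = 0.293 with estimated correlation). Hsd3b5 (-9.18 ± 0.64, 4 of 5 knockout arrays) and Cyp4a12a (-8.25 ± 0.80, n of 4 in wild-type mice) fell with Elovl3 and Slco1a1, and the highest adjusted p of these 4 was 8.36e-07.

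Of 26 macrophage genes, 20 rose and 4 fell, median 2.74 (1.87 to 3.04), adjusted p = 5.27e-06 (p = 0.389 with estimated correlation). Itgax (7.58 ± 0.47) and the lipid receptor gene Trem2 (7.19 ± 0.69, n of 3 in knockout mice) rose, and the Kupffer cell genes Cd5l (-8.56 ± 0.38) and Clec4f (-8.10 ± 0.84, 4 of 5 knockout arrays) fell (adjusted p up to 2.07e-07). Of 21 fibrosis genes, 19 rose and 0 fell, median 2.87 (2.33 to 3.1, 1.35 with normexp), adjusted p = 1.74e-10 (p = 0.293 with estimated correlation). The macrophage elastase gene Mmp12 was at least 86-fold higher (adjusted p = 1.92e-09), and the collagenase gene Mmp13 rose (5.03 ± 0.56, 3.43 floored, adjusted p = 4.98e-07, 1 of 5 wild-type arrays). Of 11 cholangiocyte genes, 9 rose and 1 fell, median 2.79 (1.94 to 2.83, 2.71 bounded, 1.65 with normexp), adjusted p = 0.000121 (p = 0.341 with estimated correlation). Prom1 (5.14 ± 0.58, 4 of 5 wild-type arrays) and Cd24a (3.82 ± 0.24) rose (adjusted p up to 5.47e-07). Of 10 neutrophil genes, 9 rose and 0 fell, median 2.60 (0.91 to 2.47, 2.31 bounded, 0.48 with normexp), adjusted p = 0.00198 (p = 0.389 with estimated correlation). Mmp8 (4.87 ± 0.54, 4.04 floored, 1 of 5 wild-type arrays) and S100a8 (2.77 ± 0.61) rose (adjusted p up to 0.00073). The endothelial genes Vwf (2.19 ± 0.25) and Lyve1 (2.08 ± 0.32) rose (adjusted p up to 1.96e-05).

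Of 15 hepatocyte genes, 0 rose and 13 fell (0 and 14 adjusted over the list alone), median -0.47 (-0.85 to -0.18, -1.37 without saturated genes), adjusted p = 0.00236 (p = 0.389 with estimated correlation). The thyroid hormone carrier gene Ttr (-2.03 ± 0.18), Tdo2 (-2.57 ± 0.33) and Hpd (-1.50 ± 0.21) fell (adjusted p up to 7.19e-06), and 6 of the 13 lower genes were saturated in 1 group. Of 23 cell cycle genes, 18 rose and 0 fell, median 1.56 (0.78 to 2.93, 0.55 with normexp), adjusted p = 2.1e-05 (p = 0.389 with estimated correlation). Mki67 rose (2.57 ± 0.40, adjusted p = 2.78e-05). Lcn2 (7.84 ± 1.17, n of 4 in knockout mice) and the metallothionein gene Mt2 (6.79 ± 0.96, saturated on 1 of 5 knockout arrays) rose (adjusted p up to 1.92e-05). The stress gene Atf3 rose (4.52 ± 0.47, adjusted p = 2.08e-07), and the cystine transporter gene Slc7a11 was at least 7.51-fold higher (adjusted p = 5.86e-14). Dct was at least 62.5-fold lower and Ifi202b at least 94.4-fold higher in knockout mice on this diet too, with adjusted p of 4.73e-12 and 5.86e-14. Genes that rose and fell in the 14 lists that did not pass (adjusted p of 0.0545 or higher) were lipid droplet (8 and 8 of 23, median -0.08, mean 0.38, test pointing up), lipoprotein (3 and 15 of 24, median -0.45), glucose (4 and 10 of 20, median -0.45) and drug metabolism (7 and 11 of 23, 9 and 11 alone, median 0.16). The other metabolic and stress lists were oxidative stress (5 and 7 of 15, median -0.22, mean 0.06, test pointing up), unfolded protein (3 and 4 of 17, 3 and 3 alone, median -0.40, mean 0.15, test pointing down), acute phase (6 and 6 of 20, 6 and 7 alone, median 0.16), interferon (1 and 2 of 20, 1 and 1 alone, median 0.08) and circadian clock (6 and 4 of 19, median 0.48). Cell markers that did not pass were T and B cell (4 and 3 of 15, median 0.57), endothelial (4 and 1 of 15, median -0.28, mean 0.20, test pointing up), red blood cell (3 and 2 of 7, median 0.04, mean -0.01, test pointing up) and adipocyte (0 and 1 of 4, median -0.59, -0.46 bounded), besides female-biased (9 and 4 of 17, median 1.93, 0.52 bounded). The female-biased list was called without wild-type Western-diet mouse 2 or 5 or knockout Western-diet mouse 3 or 5 (medians 2.29, 1.84, 1.95 and 1.97, adjusted p 0.0462, 0.0475, 0.0359 and 0.0402).

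**Figure D2:**
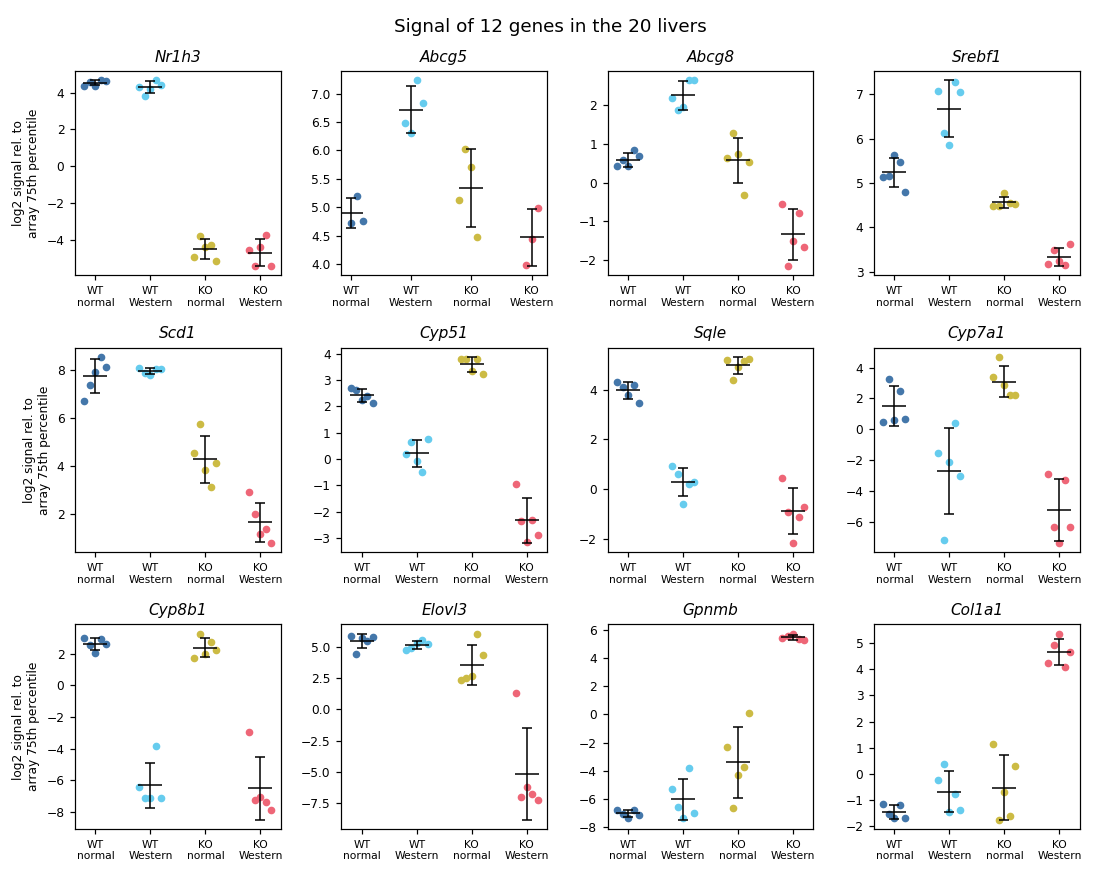
Log2 signal, relative to the 75th percentile of each array, of 12 genes in the 4 groups, with dots for arrays, bars for group means and whiskers for the SD. Gpnmb averaged 5.46 and Elovl3 -5.18 in knockout mice on Western diet, against -6 and 5.14 in wild-type mice on that diet.

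With slides as a block 4476 genes were higher and 6462 lower, all 12 lists kept their call with medians moved by at most 0.28, and 91.2% of called genes kept their direction on each of 4 slides. All 52 named calls held with the block, and Ppara changed sign on a slide. Scaling by the array median moved the median of all genes from -0.16 to -0.264. The hepatocyte list lost its call with quantile normalization (median -0.02, adjusted p = 0.222), series matrix values (-0.03, adjusted p = 0.134) and normexp (-0.21, adjusted p = 0.0671).

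The diet comparison in wild-type mice asked how normal liver answers cholesterol-rich food. Cyp8b1, the sterol hydroxylase that sets the cholic acid share of bile acids, fell (-8.93 ± 0.76, -7.56 floored, adjusted p = 2.15e-06), measured on 1 of 5 Western-diet arrays. Squalene epoxidase gene Sqle (-3.69 ± 0.36, adjusted p = 5.33e-06) and Fdps (-3.46 ± 0.32, adjusted p = 4.01e-06) fell, while lipoprotein lipase gene Lpl (4.60 ± 0.32, adjusted p = 2.22e-07) and the bile acid exporter subunit gene Slc51b (4.31 ± 0.36, adjusted p = 2.15e-06) rose. The counts were 571 higher and 476 lower of 17543 genes tested (6% changed), of which 270 and 222 differed at least 2-fold.

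Of the lipid genes Abca1 (0.51 ± 0.13, adjusted p = 0.0244), Abcg5 (1.82 ± 0.36, adjusted p = 0.0102), Abcg8 (1.67 ± 0.29, adjusted p = 0.00179), Abcg1 (1.78 ± 0.29, adjusted p = 0.00088) and Srebf1 (1.43 ± 0.23, adjusted p = 0.00088) rose. Abcg5 values came from 3 arrays on normal and 4 on Western diet, and Fasn values from 3 in each group. Fasn (-0.27 ± 0.48, adjusted p = 0.799), Scd1 (0.22 ± 0.44, adjusted p = 0.819, saturated on 4 of 5 Western-diet arrays), Ppara (-0.65 ± 0.26, adjusted p = 0.153), Cpt1a (-0.56 ± 0.24, adjusted p = 0.192) and Cd36 (0.33 ± 0.37, adjusted p = 0.664) did not pass the threshold. Of 16 LXR target genes, 6 rose and 1 fell (7 and 3 adjusted over the list alone), median 0.31 (0.07 to 0.50), adjusted p = 0.000446 (p = 0.23 with estimated correlation). Of 25 cholesterol genes, 0 rose and 23 fell (0 and 24 adjusted over the list alone), median -1.70 (-2.14 to -1.15), adjusted p = 1.34e-37 (p = 0.0106 with estimated correlation). Msmo1 fell (-2.79 ± 0.26, adjusted p = 4.01e-06) with Sqle and Fdps. Of 24 fatty acid synthesis genes, 2 rose and 9 fell, median -0.41 (-1.17 to -0.08, -0.81 on 3 slides), adjusted p = 0.00338 (p = 0.425 with estimated correlation). Acss2 (-1.74 ± 0.26) and Elovl5 (-1.40 ± 0.21) fell (adjusted p up to 0.000467). Of 24 bile acid genes, 3 rose and 8 fell (4 and 10 adjusted over the list alone), median -0.35 (-0.47 to -0.19), adjusted p = 0.0158 (p = 0.415 with estimated correlation). Cyp7a1, the first enzyme of bile acid synthesis, fell (-4.18 ± 1.13, adjusted p = 0.0337), measured on 4 of 5 Western-diet arrays.

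Of 30 fatty acid oxidation genes, 1 rose and 2 fell, median -0.22 (-0.28 to 0.07, adjusted p = 0.0574 blocked, -0.08 with quantile normalization), adjusted p = 0.00552 (p = 0.458 with estimated correlation). Of 22 lipid droplet genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone), median -0.28 (-0.44 to -0.18, -0.18 with median scaling), adjusted p = 0.00253 (p = 0.281 with estimated correlation). Mogat1 (-2.04 ± 0.44) and Lpin1 (-2.04 ± 0.46) fell (adjusted p up to 0.011). Of 24 lipoprotein genes, 1 rose and 3 fell (2 and 5 adjusted over the list alone), median -0.34 (-0.46 to -0.27, adjusted p = 0.0526 blocked, -0.14 in the series matrix), adjusted p = 0.0189 (p = 0.415 with estimated correlation). Of 20 glucose genes, 0 rose and 3 fell, median -0.32 (-0.48 to -0.25, -0.11 with quantile normalization), adjusted p = 7.97e-05 (p = 0.23 with estimated correlation). The glycolytic regulator gene Pfkfb1 (-1.41 ± 0.27, adjusted p = 0.00338) and Igfbp1, a fasting-induced binding protein gene, fell (-2.45 ± 0.62, adjusted p = 0.0266, n of 4 on Western diet). Ces2a rose (1.72 ± 0.31, adjusted p = 0.00205), and the sulfotransferase gene Sult1e1 fell (-2.69 ± 0.68, adjusted p = 0.024). The female-biased Cyp3a16 (3.11 ± 0.32) and Cyp3a44 (2.72 ± 0.26), saturated on 1 and 2 of 5 Western-diet arrays, rose (adjusted p up to 1.13e-05). Of 13 male-biased genes, 0 rose and 2 fell, median -0.33 (-0.32 to -0.18, -0.07 in the series matrix), adjusted p = 0.029 (p = 0.431 with estimated correlation). Susd4 fell (-2.97 ± 0.37, adjusted p = 5.98e-05). Of 15 hepatocyte genes, 0 rose and 1 fell, median -0.29 (-0.53 to -0.24, -0.01 in the series matrix), adjusted p = 0.000603 (p = 0.415 with estimated correlation). Of 20 acute phase genes, 0 rose and 1 fell, median -0.27 (-1.01 to 0.06, -0.03 with quantile normalization), adjusted p = 0.0116 (p = 0.425 with estimated correlation).

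Of 23 cell cycle genes, 10 rose and 0 fell (18 and 0 adjusted over the list alone), median 1.31 (0.00 to 1.86, 1.08 bounded, 0.42 with normexp), adjusted p = 1.1e-13 (p = 0.23 with estimated correlation). Mki67 (2.09 ± 0.40, adjusted p = 0.0037) and Cdc20 (2.56 ± 0.52, adjusted p = 0.00523) rose. Of 11 cholangiocyte genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone), median 0.65 (0.48 to 0.74, 0.50 bounded, 0.12 with normexp without outliers), adjusted p = 0.000145 (p = 0.281 with estimated correlation). Krt23 rose (3.88 ± 0.43, adjusted p = 2.5e-05), as did Spp1, the osteopontin gene (1.69 ± 0.38, adjusted p = 0.0119). Of 26 macrophage genes, 0 rose and 0 fell, median 0.81 (0.06 to 1.29, 0.78 bounded, 0.38 with normexp), adjusted p = 0.000145 (p = 0.425 with estimated correlation). Cd5l did not pass the threshold (1.29 ± 0.38, adjusted p = 0.0529). Of 20 interferon genes, 0 rose and 0 fell, median 1.00 (-0.15 to 0.96, 0.55 with normexp), adjusted p = 5.11e-05 (p = 0.425 with estimated correlation). The interferon-inducible Ifi44 did not pass it either (3.19 ± 1.08, adjusted p = 0.0956, 4 of 5 normal-diet arrays). Of 10 neutrophil genes, 0 rose and 0 fell (4 and 0 adjusted over the list alone), median 1.01 (0.02 to 1.76, 0.63 bounded, 0.15 with normexp without outliers), adjusted p = 0.00253 (p = 0.415 with estimated correlation). In the 10 lists that did not pass (adjusted p 0.0864 to 0.964), genes that rose and fell were drug metabolism (3 and 5 of 23, 6 and 6 alone, median -0.18, mean 0.07, test pointing down), oxidative stress (1 and 0 of 15, 2 and 0 alone, median 0.19), unfolded protein (0 and 1 of 17, median -0.09), circadian clock (0 and 0 of 19, median -0.08) and female-biased (4 and 3 of 17, 4 and 4 alone, median -0.38, -0.22 bounded, mean 0.09, test pointing up). Cell markers that did not pass were T and B cell (0 and 0 of 15, median 0.22), fibrosis (0 and 0 of 21, median 0.10), endothelial (0 and 0 of 15, median 0.02), red blood cell (1 and 0 of 7, median 0.26, 0.08 bounded) and adipocyte (0 and 0 of 4, median -0.36). Of the 16 that passed, only the cholesterol list did so with an estimated correlation.

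With slides as a block 585 genes rose and 616 fell, 14 of the 16 lists kept their call with medians moved by at most 0.37, and 94.3% of called genes kept their direction on each of 4 slides. Of 27 named calls, 26 held with the block (not Abcg5), Cd5l was called too (1.2, adjusted p = 0.0452), and Cdc20 changed sign on a slide. Counts were 311 lower without wild-type normal-diet mouse 4, 372 higher and 315 lower without wild-type Western-diet mouse 1, and 356 and 312 without wild-type Western-diet mouse 2. Abca1 was not called without wild-type normal-diet mouse 4 or 5 or Western-diet mouse 1, 3 or 5 (values 0.45 to 0.50, adjusted p 0.051 to 0.0707). Cyp7a1 was not called without normal-diet mouse 2 or 4 or Western-diet mouse 2 or 5 (-4.09 to -3.07, adjusted p 0.0612 to 0.0867). The same held for Igfbp1 without normal-diet mouse 1, 3, 4 or 5 or Western-diet mouse 3 or 5 (-2.47 to -1.87, adjusted p 0.0514 to 0.0771). Sult1e1 was not called without normal-diet mouse 3 or 4 or Western-diet mouse 1 or 2 (-2.59 to -2.03, adjusted p 0.0519 to 0.0666).

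Small list shifts in this comparison rested on single mice. Without wild-type normal-diet mouse 4 the bile acid (median -0.33), lipoprotein (-0.27) and male-biased (-0.24) lists were not called, with adjusted p of 0.0652, 0.116 and 0.0843. Without Western-diet mouse 3 the fatty acid synthesis (-0.45), bile acid (-0.34), lipoprotein (-0.31), acute phase (-0.26) and male-biased (-0.33) lists were not called, with adjusted p from 0.054 to 0.0627. The acute phase list (-0.26, adjusted p = 0.178) was not called without normal-diet mouse 2. The hepatocyte median was -0.17 without normal-diet mouse 4, and the interferon median 0.40 without Western-diet mouse 1. The red blood cell (0.22), T and B cell (0.31) and oxidative stress (0.19) lists were called without Western-diet mouse 2, 4 and 5 in turn, with adjusted p of 0.0486, 0.0431 and 0.0488. Scaling by the array median moved the median of all genes from -0.03 to 0.076, and 367 genes were then higher and 187 lower (66.2% higher against 54.5%). Background correction by normexp gave 64 and 82 (43.8% higher), and 381 and 480 (44.3%) when fitted without outlier spots. With quantile normalization the bile acid, fatty acid oxidation, lipoprotein, acute phase, hepatocyte and male-biased lists were not called (medians -0.25 to -0.02, adjusted p 0.123 to 0.313), nor the neutrophil list with normexp (0.23, adjusted p = 0.0664).

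In knockout mice the same diet comparison asked how liver lacking LXR responds. Cholesterol synthesis genes fell, with Cyp51, the lanosterol demethylase gene, at -5.93 ± 0.32, adjusted p = 2.3e-10. Sqle (-5.86 ± 0.36, adjusted p = 7.67e-10) and Idi1 (-5.76 ± 0.33, adjusted p = 4.46e-10) fell with it. Gpnmb rose (8.83 ± 0.87, adjusted p = 1.86e-07), measured on 4 of 5 normal-diet arrays, and Col1a1 rose (5.20 ± 0.47, adjusted p = 7.38e-08). The counts were 3971 higher and 4874 lower of 17548 genes tested (50.4% changed), with 2240 and 1904 at least 2-fold.

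Scd1 (-2.63 ± 0.44, adjusted p = 7.27e-05), Srebf1 (-1.23 ± 0.23, adjusted p = 0.000239), Fasn (-2.92 ± 0.53, adjusted p = 0.00134) and Abcg8 (-1.92 ± 0.29, adjusted p = 2.78e-05) fell. Lpl (3.95 ± 0.32, adjusted p = 2.33e-08) and Abcg1 (2.87 ± 0.29, adjusted p = 2.37e-07) rose, while Abca1 (-0.02 ± 0.13, adjusted p = 0.892) and Abcg5 (-0.86 ± 0.36, adjusted p = 0.0639) did not pass the threshold. Fasn had 2 normal-diet and 3 Western-diet arrays, and Abcg5 4 and 3. Of 25 cholesterol genes, 0 rose and 25 fell, median -3.70 (-4.13 to -3.57), adjusted p = 3.26e-20 (p = 0.131 with estimated correlation). Of 24 fatty acid synthesis genes, 2 rose and 20 fell, median -1.32 (-1.70 to -1.30), adjusted p = 9.99e-07 (p = 0.233 with estimated correlation). Thrsp (-4.53 ± 0.58), Acss2 (-3.80 ± 0.26) and Elovl6 (-3.30 ± 0.23) fell (adjusted p up to 3.74e-06). Of 24 bile acid genes, 2 rose and 16 fell, median -1.28 (-1.60 to -0.97), adjusted p = 3.29e-05 (p = 0.145 with estimated correlation). Cyp8b1 (-8.86 ± 0.76, -7.29 floored, adjusted p = 3.9e-08, 1 of 5 Western-diet arrays) and Cyp7a1 (-8.32 ± 1.13, -7.55 floored, adjusted p = 7.26e-06, 2 of 5) fell, and Slc51b rose (5.31 ± 0.36, adjusted p = 3.1e-09). Of 30 fatty acid oxidation genes, 1 rose and 24 fell, median -1.2 (-1.79 to -0.71), adjusted p = 5.85e-08 (p = 0.258 with estimated correlation). Cyp4a10 (-4.22 ± 0.25) and Ppara (-1.72 ± 0.26) fell (adjusted p up to 2.09e-05), and Cpt1a did not pass the threshold (-0.41 ± 0.24, adjusted p = 0.163).

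Cidec (3.59 ± 0.35) and Cd36 (1.76 ± 0.37) rose and Fitm1 fell (-5.31 ± 0.54, -4.32 floored, 2 of 5 Western-diet arrays), adjusted p up to 0.000677. Of 24 lipoprotein genes, 2 rose and 13 fell, median -0.53 (-0.78 to -0.21, adjusted p = 0.0818 blocked, 0.01 with quantile normalization), adjusted p = 0.0288 (p = 0.347 with estimated correlation). Of 21 glucose genes, 1 rose and 12 fell, median -0.60 (-1.29 to -0.37, -0.25 in the series matrix), adjusted p = 0.00752 (p = 0.314 with estimated correlation). Of 23 drug metabolism genes, 1 rose and 12 fell, median -0.52 (-0.79 to -0.32, -0.06 with quantile normalization), adjusted p = 0.0149 (p = 0.314 with estimated correlation). Cyp1a2 (-3.83 ± 0.23) and Cyp2c29 (-2.56 ± 0.16) fell (adjusted p up to 1.1e-09). Of 13 male-biased genes, 0 rose and 13 fell, median -4.92 (-5.80 to -2.41, -3.19 for genes above background on all arrays), adjusted p = 1.34e-09 (p = 0.135 with estimated correlation). Elovl3 (-8.75 ± 1.2, -7.63 floored) and Slco1a1 (-8.04 ± 0.69, -7.15 floored), each measured on 1 of 5 Western-diet arrays, fell with Cyp4a12a (-7.75 ± 0.80, n of 4 on normal diet) and Hsd3b5 (-7.48 ± 0.64, 4 of 5), adjusted p up to 8.49e-06. Of 15 hepatocyte genes, 0 rose and 15 fell, median -0.54 (-0.80 to -0.36, -1.61 without saturated genes, 0.01 with quantile normalization), adjusted p = 4.32e-05 (p = 0.258 with estimated correlation). Ttr (-1.95 ± 0.18), Tdo2 (-2.72 ± 0.33) and Hpd (-2.07 ± 0.21) fell (adjusted p up to 2.18e-06), and 8 of the 15 lower genes were saturated in 1 group.

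Of 26 macrophage genes, 20 rose and 1 fell, median 2.01 (0.80 to 3.02), adjusted p = 5.13e-07 (p = 0.314 with estimated correlation). Trem2 (6.81 ± 0.69, n of 3 on Western diet) and Lgals3 (5.54 ± 0.42) rose (adjusted p up to 5.93e-07). Of 21 fibrosis genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone), median 2.47 (1.35 to 3.52, 1.15 with normexp), adjusted p = 6.18e-10 (p = 0.145 with estimated correlation). Col3a1 (3.74 ± 0.35) and Mmp12 (7.63 ± 0.56, 5.93 floored, 1 of 5 normal-diet arrays) rose (adjusted p up to 1.23e-07). Of 11 cholangiocyte genes, 11 rose and 0 fell, median 2.42 (1.59 to 4.22, 1.5 with normexp), adjusted p = 3.83e-07 (p = 0.145 with estimated correlation). Prom1 (6 ± 0.58, 3 of 5 normal-diet arrays) and Cd24a (2.99 ± 0.24) rose (adjusted p up to 1.49e-07). Of 10 neutrophil genes, 9 rose and 0 fell, median 3.12 (2.37 to 4.74, 2.72 bounded, 0.63 with normexp), adjusted p = 4.12e-05 (p = 0.233 with estimated correlation). Mmp8 (5.26 ± 0.54, 3.98 floored, 1 of 5 normal-diet arrays) and S100a8 (4.21 ± 0.61) rose (adjusted p up to 1.5e-05). Of 23 cell cycle genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone), median 1.13 (-0.02 to 2.35, 0.47 with normexp), adjusted p = 0.000153 (p = 0.431 with estimated correlation). Slc7a11 was at least 6.96-fold higher (adjusted p = 3.09e-13), and Atf3 rose (3.71 ± 0.47, adjusted p = 3.3e-06). The carboxypeptidase gene Cpe rose (6.06 ± 0.25, adjusted p = 7.83e-12). In the 12 lists that did not pass (adjusted p 0.152 to 0.98), genes that rose and fell were LXR target (4 and 7 of 16, 4 and 8 alone, median -0.76), lipid droplet (7 and 9 of 22, 8 and 10 alone, median -0.22, mean -0.04, test pointing up), oxidative stress (6 and 6 of 15, median 0.13), unfolded protein (2 and 2 of 17, 1 and 0 alone, median 0.06), acute phase (4 and 7 of 20, 5 and 7 alone, median -0.14, mean 0.39, test pointing up) and interferon (1 and 1 of 20, 0 and 1 alone, median 0.19). The others were T and B cell (2 and 4 of 15, median -0.46), endothelial (4 and 4 of 15, 4 and 5 alone, median -0.36), red blood cell (1 and 1 of 7, median -0.10), adipocyte (0 and 2 of 4, median -1.51), circadian clock (1 and 4 of 19, median -0.57) and female-biased (5 and 6 of 17, median -0.39). None of the 14 that passed did so with an estimated correlation.

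With slides as a block 4288 genes rose and 6008 fell, 13 of the 14 lists kept their call with no median moved by over 0.06, 88.8% of called genes kept their direction on each of 5 slides, and all 42 named calls held with the block and on every slide. The larger side turned with quantile normalization (4774 higher and 4176 lower), in the series matrix (4393 and 3949), with normexp (1803 and 1768) and at 2-fold. Quantile normalization moved the median of all genes from -0.119 to -0.012 and normexp moved it to -0.234, and with normexp fitted without outlier spots 3353 genes were higher and 6715 lower (33.3% higher against 44.9%). With quantile normalization the lipoprotein (adjusted p = 0.496), hepatocyte (adjusted p = 0.0719), glucose (-0.26, adjusted p = 0.129) and drug metabolism (-0.06, adjusted p = 0.21) lists were not called.

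Both genotypes and both diets shared part of their changes. Across 17540 genes, which are not independent replicates, the genotype differences on the 2 diets had Pearson r = 0.64 and Spearman rho = 0.61, and 1540 genes were higher on both diets (497.1 for independent lists) and 1154 lower on both (481.9), besides 124 opposite. The diet differences in the 2 genotypes had r = 0.43 and rho = 0.45, with 350 genes higher in both (129.3), 366 lower in both (132.3) and 61 opposite.

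The interaction tested whether the diet difference in knockout mice differed from that in wild-type mice. Cpe (6.56 ± 0.36, adjusted p = 1.08e-09), Trem2 (5.84 ± 0.91, adjusted p = 0.000207, n of 3 in knockout mice on Western diet) and Col1a1 (4.43 ± 0.66, adjusted p = 9.63e-05) had higher diet differences in knockout mice. So did the osteoclast and macrophage protease gene Ctsk (5.85 ± 0.55, 6.06 floored, adjusted p = 9.32e-07), but it was well above background on 1 of 5 arrays in each wild-type group, so that its diet difference in wild-type mice was hardly measured. Elovl3 (-8.42 ± 1.70, -7.31 floored, adjusted p = 0.00122), Cyp4a12a (-7.90 ± 1.13, adjusted p = 9.65e-05) and Slco1a1 (-7.48 ± 0.97, -6.58 floored, adjusted p = 2.58e-05) had lower ones. Elovl3 and Slco1a1 were measured on 1 of 5 knockout Western-diet arrays, and Cyp4a12a had n of 4 in wild-type mice on Western diet and knockout mice on normal diet. In all, 2259 genes had a higher and 2580 a lower diet difference of 17540 tested (27.6%), and 1658 and 1153 of them differed at least 2-fold.

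Diet differences were lower in knockout mice for Abca1 (-0.53 ± 0.18, adjusted p = 0.0371), Abcg5 (-2.69 ± 0.51, adjusted p = 0.002), Abcg8 (-3.59 ± 0.42, adjusted p = 8.22e-06), Srebf1 (-2.67 ± 0.33, adjusted p = 1.58e-05), Scd1 (-2.85 ± 0.62, adjusted p = 0.00229) and Fasn (-2.65 ± 0.72, adjusted p = 0.0224), while Cyp7a1 did not pass the threshold (-4.15 ± 1.59, -3.75 floored, adjusted p = 0.0611, 4 of 5 wild-type and 2 of 5 knockout Western-diet arrays). Scd1 was saturated on 4 of 5 wild-type Western-diet arrays, and Abcg5 and Fasn had n of 2 to 4 per group. In the lists below, "rose" and "fell" mean a higher or lower diet difference in knockout mice. Of 16 LXR target genes, 2 rose and 8 fell (3 and 9 adjusted over the list alone), median -0.82 (adjusted p = 0.0799 blocked, -0.51 with normexp), adjusted p = 0.014 (p = 0.338 with estimated correlation). Of 24 fatty acid synthesis genes, 1 rose and 12 fell (1 and 15 adjusted over the list alone), median -1.05, adjusted p = 3.75e-05 (p = 0.338 with estimated correlation). Of 25 cholesterol genes, 0 rose and 22 fell, median -1.69, adjusted p = 5.64e-13 (p = 0.149 with estimated correlation). Cyp51 (-3.73 ± 0.45) and Tm7sf2 (-3.48 ± 0.31) were lower (adjusted p up to 1.32e-05). Of 24 bile acid genes, 1 rose and 14 fell (1 and 16 adjusted over the list alone), median -0.96 (-0.59 with normexp), adjusted p = 3.73e-05 (p = 0.149 with estimated correlation). Cyp7b1 (-4.11 ± 0.32) and Slc10a1 (-2.38 ± 0.43) were lower (adjusted p up to 0.000536). Of 30 fatty acid oxidation genes, 0 rose and 17 fell (1 and 21 adjusted over the list alone), median -0.88 (-0.58 with normexp), adjusted p = 1.14e-06 (p = 0.338 with estimated correlation). Cyp4a10 (-4.28 ± 0.35), Ehhadh (-3.19 ± 0.37) and Acot1 (-3.53 ± 0.71, n of 4 in wild-type mice on normal diet) were lower with adjusted p up to 0.00133, Ppara was lower (-1.07 ± 0.36, adjusted p = 0.0345), and Cpt1a did not pass the threshold (0.15 ± 0.34, adjusted p = 0.797).

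Cidec was higher (3.55 ± 0.50, adjusted p = 5.46e-05), and Cd36 did not pass the threshold (1.43 ± 0.53, adjusted p = 0.0506). Of 23 drug metabolism genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone), median -0.57 (-0.21 with normexp), adjusted p = 0.00512 (p = 0.338 with estimated correlation). Of 26 macrophage genes, 13 rose and 2 fell, median 1.31, adjusted p = 3.75e-05 (p = 0.476 with estimated correlation). Of 21 fibrosis genes, 17 rose and 0 fell, median 2.23 (1.16 with normexp), adjusted p = 1.86e-11 (p = 0.149 with estimated correlation). Timp1 was higher (3.80 ± 0.45, adjusted p = 9.2e-06). Of 10 neutrophil genes, 5 rose and 0 fell, median 2.09 (0.37 with normexp), adjusted p = 0.00155 (p = 0.338 with estimated correlation). Of 11 cholangiocyte genes, 8 rose and 1 fell, median 2.01 (1.18 on 3 slides), adjusted p = 0.000105 (p = 0.325 with estimated correlation). Of 15 hepatocyte genes, 0 rose and 5 fell, median -0.26 (-1.2 without saturated genes, 0.09 with normexp), adjusted p = 0.00456 (p = 0.476 with estimated correlation). Ttr (-1.66 ± 0.25) and Tdo2 (-2.56 ± 0.47) were lower (adjusted p up to 0.000544). Of 13 male-biased genes, 0 rose and 12 fell, median -3.71, adjusted p = 3.34e-11 (p = 0.149 with estimated correlation). Lcn2 was higher (5.81 ± 1.60, adjusted p = 0.0118, n of 4 in knockout mice on Western diet). In the 14 lists that did not pass (adjusted p 0.0941 to 0.844), higher and lower genes were lipid droplet (7 and 3 of 22, 9 and 3 alone, median -0.03, mean 0.44, test pointing up), oxidative stress (2 and 3 of 15, median -0.30, mean 0.04, test pointing down), interferon (0 and 2 of 20, 0 and 0 alone, median -1.03), endothelial (2 and 2 of 15, median -0.42) and cell cycle (1 and 0 of 23, 0 and 0 alone, median -0.24) among others. In the cell cycle list Mcm2, a replication helicase gene, was higher (1.5 ± 0.49, adjusted p = 0.0281). None of the 12 that passed did so with an estimated correlation.

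**Figure D3:**
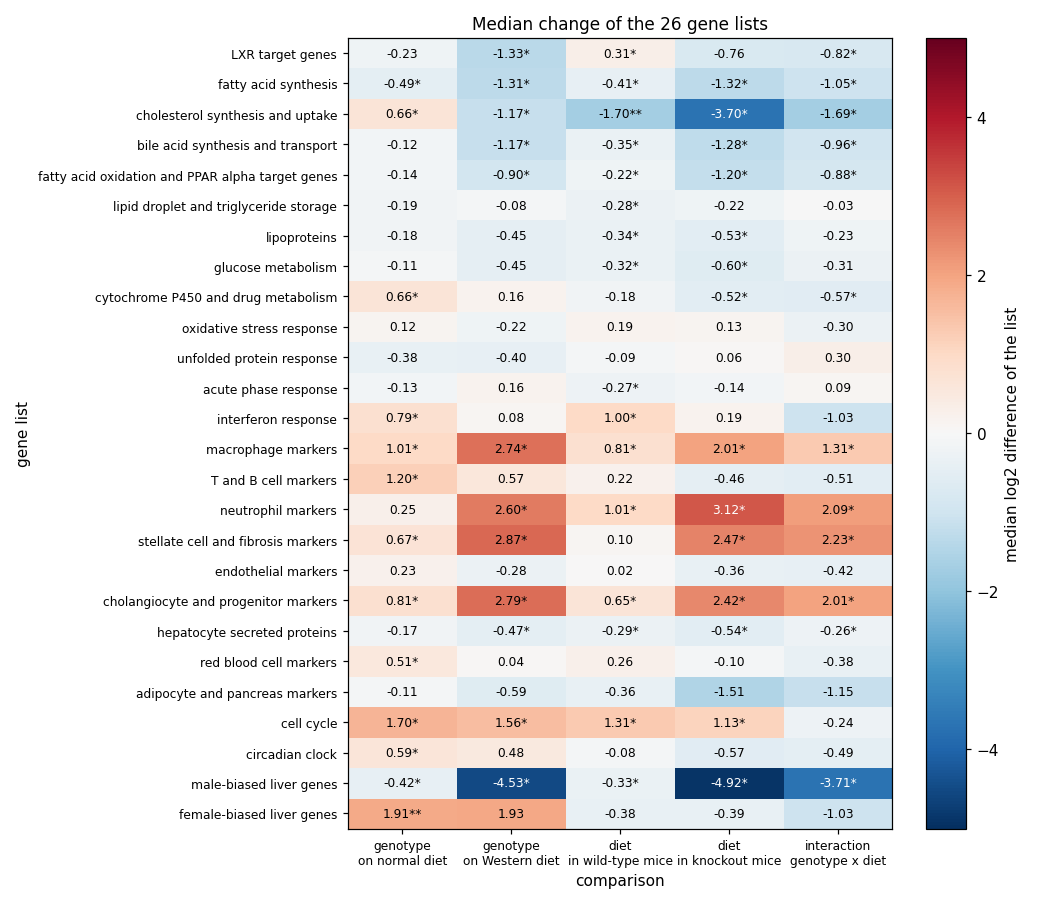
Median log2 difference of 26 gene lists in 5 comparisons. One star marks lists past the test with a preset correlation and a double star those past it with an estimated one too (female-biased, 1.91, for genotype on normal diet and cholesterol, -1.70, for diet in wild-type mice).

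With slides as a block 2476 genes had higher and 3048 lower diet differences, 11 of the 12 lists kept their call with medians moved by at most 0.19, and 25 of the 27 named calls held (not Fasn or Ppara). Normexp gave 636 higher and 378 lower genes (62.7% higher against 46.7%), quantile normalization 2551 and 2307 and the series matrix 2614 and 2152. Normexp moved the median of all genes from -0.078 to -0.203. With it the LXR (-0.51), drug metabolism (-0.21), neutrophil (0.37) and hepatocyte (0.09) lists were not called (adjusted p 0.0604, 0.0648, 0.052 and 0.332). Abca1 was not called without 1 of wild-type normal-diet mice 3, 4 and 5, wild-type Western-diet mice 1, 3, 4 and 5, knockout normal-diet mice 4 and 5 or knockout Western-diet mice 2, 3 and 5 (-0.53 to -0.45, adjusted p 0.0543 to 0.0723). For Ppara these were wild-type normal-diet mice 1, 2 and 3, wild-type Western-diet mice 4 and 5, knockout normal-diet mice 2 and 3 and knockout Western-diet mice 2, 3 and 5 (-1.04 to -0.93, adjusted p 0.0555 to 0.0685). Fasn was not called without knockout normal-diet mouse 5 (-2.37, adjusted p = 0.0765) or knockout Western-diet mouse 3 (-2.38, adjusted p = 0.0523), nor Mcm2 without wild-type normal-diet mouse 1, wild-type Western-diet mouse 3 or 5 or knockout normal-diet mouse 2 (1.24 to 1.36, adjusted p 0.0519 to 0.0548). The interferon list was called without wild-type Western-diet mouse 3 or 5 or knockout normal-diet mouse 4 (medians -1.24, -1.15 and -1.30, adjusted p 0.0118, 0.0492 and 0.0221), and the lipoprotein list without wild-type normal-diet mouse 4 (-0.37, adjusted p = 0.0274). The hepatocyte median was -0.40 without that mouse and -0.17 without knockout normal-diet mouse 3, and the drug metabolism median -0.86 without wild-type Western-diet mouse 1.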

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

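The comparison with endothelial genes, the comparison with matched random lists and the tests around Nr1h3 and Nr1h2 taken singly were tests chosen only after the result was seen. Of 436 groups of 5 arrays tested over the named genes and quality measures, 31 had 1 array far from the others, where chance gives about 1 in 20 groups (21.8). The value is the gap to the nearest other array as a share of the range of the group, and the end at which the array lay is given.

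Knockout normal-diet mouse 2 stood apart for Clec4f (0.773, low), Cyp4a10 (0.754, high), Ehhadh (0.763, high) and Msmo1 (0.711, low). Knockout Western-diet mouse 1 lay apart for Cd79b (0.796, high), Cyp8b1 (0.833, high), Elovl3 (0.873, high) and Fdps (0.715, high). Wild-type normal-diet mouse 2 was separate for Cd5l (0.823, high), Clec4f (0.868, high) and Elovl3 (0.745, low). Wild-type Western-diet mouse 2 stood out for Abca1 (0.752, low), Spp1 (0.881, high) and Ttr (0.901, low). Knockout normal-diet mouse 3 stood apart for Mylip (0.731, low) and Srebf1 (0.735, high). Knockout normal-diet mouse 4 lay apart for Cd244a (0.728, low) and Itgax (0.844, low). Knockout Western-diet mouse 5 was separate for Ces2a (0.878, low) and the number of saturated probes (0.75, high). Wild-type normal-diet mouse 1 stood out for Usp2 (0.739, low) and the number of spots marked as outliers (0.75, high). Wild-type Western-diet mouse 1 stood apart for Mmp13 (0.849, high) and Nlrp12 (0.729, low). Wild-type Western-diet mouse 4 lay apart for Abcb11 (0.75, high) and Cyp8b1 (0.784, high). Knockout normal-diet mouse 5 was separate for Mmp12 (0.887, high). Wild-type normal-diet mouse 4 stood out for Ifi44 (0.883, low). Wild-type normal-diet mouse 5 stood apart for Mmp13 (0.793, high). Wild-type Western-diet mouse 3 lay apart for Thrsp (0.782, low). Wild-type Western-diet mouse 5 was separate for Tm7sf2 (0.774, high).

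The diet difference in knockout minus wild-type mice (log2) differed from 0 for 65 named genes, besides 9 not given here because they lay below background on every array of a group. Among cholesterol and bile acid genes these were Abca1 (-0.53), Abcg5 (-2.69), Abcg8 (-3.59), Abcb11 (-0.80), Abcc4 (1.55), Cyp51 (-3.73), Cyp7b1 (-4.11), Fdps (-1.69), Idi1 (-3.14), Msmo1 (-1.63), Slc10a1 (-2.38), Slco1a1 (-7.48), Slco1a4 (-1.33), Sqle (-2.16) and Tm7sf2 (-3.48). Among fatty acid and storage genes these were Acot1 (-3.53), Acss2 (-2.06), Cidea (3.02), Cidec (3.55), Cyp4a10 (-4.28), Ehhadh (-3.19), Elovl3 (-8.42), Elovl6 (-2.31), Fasn (-2.65), Fitm1 (-4.19), Plin2 (1.24), Ppara (-1.07), Scd1 (-2.85), Scd2 (-3.90), Srebf1 (-2.67) and Thrsp (-3.12). Among immune and matrix genes these were Cd5l (-1.95), Cd79b (-1.83), Clec4f (-4.22), Col1a1 (4.43), Col3a1 (3.16), Ctsk (5.85), Itgax (3.27), Lcn2 (5.81), Lgals3 (4.30), Nlrp12 (4.56), S100a8 (2.63), Timp1 (3.80), Trem2 (5.84), Lyve1 (1.41) and Vwf (1.43). Among drug-metabolism and sex-biased genes these were Ces2a (-2.69), Cyp1a2 (-2.86), Cyp2c29 (-2.02), Cyp3a16 (-3.50), Cyp3a44 (-2.99), Cyp4a12a (-7.90), Hsd3b5 (-6.95) and Susd4 (-3.71). The remaining genes were Atf3 (2.61), Cd24a (2.34), Cpe (6.56), Hpd (-1.34), Igfbp1 (3.22), Krt23 (-1.78), Mcm2 (1.5), Mt2 (4.98), Tdo2 (-2.56), Ttr (-1.66) and Usp2 (-2.22). Saturated were Scd1 (4 wild-type Western-diet arrays, 1 on normal diet), Cyp3a44 (2 wild-type Western-diet, 1 knockout normal-diet), Cyp3a16 (1 wild-type Western-diet) and Mt2 (1 knockout Western-diet), and Clec4f, Ctsk, Elovl3, Fitm1, Hsd3b5, Itgax, Nlrp12, S100a8 and Slco1a1 were well above background on fewer than 5 arrays of a group, so that their values are less exact. Against the other genes 12 lists shifted with the preset correlation, none with an estimated correlation (adjusted p 0.149 to 0.476), and the LXR list not with slides as a block (adjusted p = 0.0799). Their medians were LXR (-0.82), fatty acid synthesis (-1.05), cholesterol (-1.69), bile acid (-0.96), fatty acid oxidation (-0.88), drug metabolism (-0.57), macrophage (1.31), neutrophil (2.09), fibrosis (2.23), cholangiocyte (2.01), hepatocyte (-0.26) and male-biased (-3.71).

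Macrophage, fibrosis and cholangiocyte genes rose in knockout mice on Western diet, with medians of 2.74, 2.87 and 2.79 (adjusted p = 0.389, 0.293 and 0.341 with an estimated correlation), though 4 of 26 macrophage genes fell. A lower share of hepatocyte RNA would raise endothelial genes alike. Of these 15, 4 rose (Vwf 2.19, Lyve1 2.08) and 1 fell (mean 0.20, test pointing up). Their median of -0.28 lay 3.02 below the lowest of the 3 lists (95% bootstrap interval over genes, not mice, 1.26 to 3.22). This argues against a lower share alone only if endothelial genes were steady within cells. Scaling was argued against, since the lowest of the 3 medians over the scaling and background alternatives was 1.35. A gain of macrophages, matrix-producing and bile duct cells may underlie the pattern, and neither cell counts nor a change within a cell type were tested.

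Male-biased genes fell in knockout mice on Western diet, with a median of -4.53 over 13 genes (adjusted p = 0.293 with an estimated correlation). Female or mixed-up mice were argued against by Y-linked genes, whose median difference was -0.55. A general loss of liver transcripts was argued against by 10000 random lists of genes of like signal, of which 95% had medians of -0.84 to -0.15 and the lowest -1.70. A loss of the hormone-driven male programme under the diet in knockout mice could explain the fall, and no hormone was measured.

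Genes that differed between genotypes on normal diet could in part reflect strain DNA around the targeted genes. Within 10 Mb of Nr1h3 or Nr1h2, 64 of 321 genes were called (19.9%) against 3371 of 17100 elsewhere (19.7%), a ratio of 1.01 (95% interval 0.811 to 1.26, two-sided Fisher's exact p = 0.944). The regions went opposite ways, so that this decides nothing. Around Nr1h3 alone the ratio was 0.423 (11 of 132, 0.24 to 0.745, Fisher's exact p = 0.000568). Around Nr1h2 alone it was 1.42 (53 of 189, 1.13 to 1.79, Fisher's exact p = 0.00578). A regional share cannot clear single genes, so strain DNA stays open for all 64 beside a direct effect. Dct and nearby Abcc4 on chromosome 14 and Ifi202b and Cd244a on chromosome 1 lie on other chromosomes than Nr1h3 and Nr1h2. Strain differences there, on the mixed Sv129/C57Bl6J background, were not tested.

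Chance could be excluded, were the arrays independent, for the 4 counts between groups, since of 100 splits of the arrays only the real one (1) gave as many genes. The splits took no account of slides, although arrays on the same slide were correlated. The real counts were 3460 for genotype on normal diet, 10128 for genotype on Western diet, 1047 for diet in wild-type mice and 8845 for diet in knockout mice. The highest of the other splits gave 1665, 5557, 5 and 6347, and at most 8, 0, 5 and 5 where 2 arrays of each group were exchanged rather than 1. For the interaction, regroupings of the residuals of the additive model gave at most 2987 genes against 4839, again with only the real grouping (1) as large.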

How the results depend on the processing

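Leaving out saturated genes, using only the 3 slides with all 4 groups, and fitting normexp without spots marked as outliers were tests chosen only after seeing the data. Every other alternative was chosen beforehand and all were run. Counts below are given as higher and lower genes, and the cause of a difference was not tested unless it is stated.

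Asking for at least a 2-fold difference, which can only remove genes, left 1253 and 382 genes for genotype on normal diet, 2861 and 1995 for genotype on Western diet, 270 and 222 for diet in wild-type mice and 2240 and 1904 for diet in knockout mice. For the interaction it left 1153 lower genes. Normexp gave 307 and 202, 1971 and 2331, 64 and 82, and 1803 and 1768 in the same order, and 636 and 378 for the interaction. Its fitted noise SD reached 523 on an array, and was 0.966 or less on every array when all foreground and background outliers were left out of the fit. Fitted so, it gave 1090 higher and 1197 lower genes for genotype on normal diet, which turns the balance, and its other counts were within 1.5 times of the reported ones.

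Median scaling gave 367 and 187 genes for diet in wild-type mice and 1702 lower ones for the interaction. The 3 slides with all 4 groups, which hold 12 arrays, gave 649 and 258 genes for genotype on normal diet, 97 and 89 for diet in wild-type mice and 1044 and 742 for the interaction. They gave 3797 lower genes for genotype on Western diet and 3056 for diet in knockout mice. Genes well above background on all 20 arrays (13784 tested) gave 1319 higher ones for genotype on normal diet, and array weights, which ran from 0.49 to 2.45, gave 2479 lower ones. Testing each probe on its own, which tests more features, gave 9351 lower probes for genotype on Western diet, 7901 for diet in knockout mice and 4051 for the interaction.

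Without wild-type Western-diet mouse 4 the larger side turned for diet in wild-type mice (430 and 524). With 1 array left out, higher genes ran from 1556 to 2197 and lower ones from 967 to 1930 for genotype on normal diet, and from 4095 to 4447 and 5313 to 5921 for genotype on Western diet. For diet in wild-type mice they ran from 356 to 624 and 311 to 524, for diet in knockout mice from 3594 to 4020 and 4373 to 5072, and for the interaction from 1922 to 2440 and 2062 to 2794.

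Among named genes, changes of sign were met only in ones that did not pass the threshold. Medians of called lists changed sign for hepatocyte genes in the interaction (-0.26 to 0.09 with normexp) and for lipoprotein (-0.53) and hepatocyte genes (-0.54) for diet in knockout mice (0.01 for both with quantile normalization), and for T and B cell genes for genotype on normal diet (1.2 to -0.23 for genes above background on all 20 arrays). Values moved by over 1.5 times for 66 of 184 named calls (65 with normexp, 43 with normexp without outlier spots, 35 in the series matrix) and 45 of 67 medians of called lists. Abcg8 for genotype on normal diet was 0.02 with normexp, 0 with quantile normalization, 0.17 with array weights and 0.05 with the mean of probes, and ran from -0.20 to 0.20 with 1 array left out. Abca1 for diet in knockout mice was 0.23 with normexp, 0.15 with quantile normalization, 0.03 with median scaling and with array weights, 0.11 in the series matrix and 0.07 with normexp without outlier spots, and ran from -0.08 to 0.05. Cpt1a for the interaction was -0.15 with array weights and -0.17 with the mean of probes, and ran from -0.04 to 0.30. Fasn for diet in wild-type mice was 0 with normexp and ran from -0.72 to 0.15. On the 3 slides Ppara for genotype on normal diet was -0.02 and Scd1 for diet in wild-type mice was -0.06, and with 1 array left out they ran from -0.01 to 0.24 and from -0.04 to 0.42.

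Over all alternatives, 7318 of 7569 values of named genes kept their side of the threshold, 164 fell below it, 61 came past it and 26 changed sign. Of 4784 list results 4544 kept their side, 162 fell below the threshold and 78 came past it, and 65 of those that fell did so with an estimated correlation. Signal over background limits the result, since 27573 genes entered without the filter and 17552 with it.

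With replicate number as a block, 200 of 207 values of named genes kept their side and 7 fell below the threshold, and of 130 list results 129 kept theirs and 1 came past it. The numbers do not pair mice: deviations from group means of arrays with the same number had r from -0.397 to 0.488, across genes, with 10 of 30 pairs over 0.1. Pairs on the same slide had a median r of 0.373 with the same number and 0.324 with another, and pairs on different slides -0.056 and -0.048.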

Other observations

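The counts below are no tests and were taken only after the result was seen. Most genes with an interaction changed with the diet in knockout mice. Of the 2580 genes whose diet difference was lower in knockout mice, 2373 fell with the diet in knockout mice and 148 fell and 136 rose in wild-type mice, and 42 rose in wild-type and fell in knockout mice. Of the 2259 genes whose diet difference was higher, 2135 rose with the diet in knockout mice, 70 rose and 70 fell in wild-type mice, and 19 fell in wild-type and rose in knockout mice.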
